A study of Mus musculus with 6 samples.

How the data were processed

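Small RNA libraries were made from total RNA of mouse fetal liver taken on gestational day 18.5, 3 from offspring of dams on a normal diet (O-Con) and 3 from offspring of dams on a high-fat diet for 8 weeks (O-DIO). RNA was extracted with Trizol and libraries were built with an Illumina TruSeq RNA kit, per the labels' protocols. Reads were aligned with Bowtie 0.12.2 and the genome build was mm8, per the submitters' processing notes. The counting tool, the miRNA annotation release, adapter trimming and the caller of the predicted miRNAs are not given in the sources used here. The authors deposited 1 table of 1714 mature miRNAs by 6 libraries. Its values are RPM, reads per 1000000 reads, as deposited by the authors: the columns sum to 30.4 to 33.8% of the full scale, so the denominator was a library-wide read total and not the miRNA reads alone, and what that total counted is not stated. All values above 0 were whole multiples of 1 step per column, 0.0530 to 0.0599 RPM per read (100% whole within a tolerance of 0.05 reads), which gave back whole reads. The study design had foreseen raw counts or normalized values; since the unit is RPM, the test planned for normalized values was the main one. Columns were matched to libraries by name, and 0 columns were left unmatched.

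Each miRNA was analysed as log2(RPM + 1), with a pseudocount of 1 RPM. miRNAs with a mean of at least 1 RPM over the 6 libraries were kept, which left 527, 492 known and 35 predicted. The groups were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, group as the sole term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 fold changes are O-DIO minus O-Con, values in RPM are means ± SD with n = 3 per group, and errors of fold changes are standard errors. All adjusted p-values of single miRNAs and arm ratios come from limma unless edgeR or DESeq2 is named.

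The miRNAs named in the text followed a rule set before the data were examined: the 10 largest rises and 10 largest falls that passed, the 5 most abundant miRNAs, and up to 3 of the most abundant tested members of each list. Others are said to have been chosen after their values were seen. Lists set in the same way were liver-enriched, lipid and insulin related, let-7, erythroid, white blood cell, endothelial, stellate and mesenchymal, epithelial (bile duct), striated muscle, neural, pancreas, skin, Dlk1-Dio3 cluster, Sfmbt2 cluster, miR-17-92 and paralogs, inflammation induced, miR-29 family, miR-34 family, miR-290 and miR-302 clusters, and liver proliferation and fetal growth. The third member of the pancreas list was left out of the naming because its reads in O-DIO were 0 to 2 per library. Some miRNAs belong to more than 1 list, among them miR-802-5p, miR-21a-5p, miR-378a-3p and miR-143-3p. Lists with at least 3 tested members were tested against the other miRNAs with camera, at a preset correlation of 0.01 and with the correlation estimated. They were also tested with fry, which asks whether a list itself moves on balance one way. The p-values of each test were adjusted over the lists. Shares of miRNA reads and numbers of detected miRNAs were compared with exact two-sided permutation tests over 20 arrangements, whose smallest p is 0.1. For hairpins with both arms kept, the log2 ratio of the 5p to the 3p arm was tested with limma.

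Alternatives covered median-ratio, quantile and top-5-free scaling, other filters, pseudocounts of 0.1 and 10 RPM, other priors, leaving out each library, and the replicate number as a block. Added after the data were seen were scaling without the Dlk1-Dio3 cluster, leaving the cluster or the 5 most abundant miRNAs out of the test, known miRNAs alone, arm ratios with both arms at 10 RPM, and count tests on the recovered whole reads with edgeR 4.0.16 (quasi-likelihood test, minimum count 10) and DESeq2 1.42.0. edgeR with TMM called 433 of 604 miRNAs, edgeR with the deposited totals 447, and DESeq2 456 of 1598, of which 497 had no adjusted p. Libraries of one group differed from each other by more than sampling noise, with a chi-square of their counts per degree of freedom of 59.9 to 339, so none was treated as a repeat of another.

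The tests were tried on simulated reads drawn from the real means and library sizes, with 200 miRNAs changed. In the simulated comparison of O-DIO with O-Con, limma recovered 43% of 2-fold and 93% of 4-fold changes. It tested 515 miRNAs, and 0.7% of its calls were false. edgeR recovered 40% and 99% of these changes with 609 tested and 0.7% false, and DESeq2 47% and 95% with 1510 tested and 3.4% false. limma made 0 calls on unchanged data. The simulation gave all miRNAs the same dispersion and as many rises as falls. In the real data 403 of 527 miRNAs were called, 301 of them lower, so these rates need not hold there. Depth was 5083013 to 6380030 miRNA reads per library, and a count of 0 allows up to 3 reads. No coordinates are given, since the reference annotation used here was GRCm38 and not mm8. It served to match 1239 of 1312 known miRNA names and to find which hairpins neighbour each other within 10000 bases (1184 with a single locus) or overlap. Messenger RNA targets of the miRNAs were not analysed here.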

Results

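MicroRNAs (miRNAs), short RNAs that repress messenger RNAs, were sequenced in 6 libraries of mouse fetal liver taken on gestational day 18.5. In 3 libraries, named O-DIO, the dams had received a high-fat diet for 8 weeks before mating, and in the other 3, named O-Con, a normal diet; what the letter O stands for is not given in the sources used here. The deposited values are reads per 1000000 reads (RPM) of a library-wide read total for 1714 mature miRNAs, of which 1312 are known and 402 are predicted. The read total implied by the values was 18900000, 18700000 and 17800000 in O-Con 1 to 3 and 17500000, 18700000 and 16700000 in O-DIO 1 to 3. Reads assigned to miRNAs numbered 6380030, 5800436 and 5863321 in O-Con 1 to 3 and 5737244, 5794829 and 5083013 in O-DIO 1 to 3. A count of 0 allowed a level of up to 3 reads, which is 0.159 to 0.180 RPM depending on the library and covers counting error only. Across miRNAs, which are not independent replicates, Pearson's r of log2 values was 0.977 to 0.993 between O-Con libraries, 0.985 to 0.988 between O-DIO libraries and 0.713 to 0.741 between libraries of different groups. The labels do not say that the libraries came from separate fetuses or litters, so the p-values measure only the spread between these samples, which may be technical.

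The comparison of O-DIO with O-Con asked how diet-induced obesity of the dam relates to miRNA levels in the fetal liver. Any liver stage, tissue make-up, dissection or batch difference that coincides with the groups cannot be told apart from the diet in this design. The miRNAs of the imprinted Dlk1-Dio3 cluster, which are expressed from the maternally inherited chromosome, were lower by a wide margin in O-DIO: all 84 tested members fell, and their summed share of miRNA reads was 24.6% ± 0.92 in O-Con and 0.335% ± 0.057 in O-DIO (SD, n = 3 each). All 8 tested members of the list for red blood cell precursors (erythroid), several of them from shared or overlapping hairpins, fell as well, 7 under every scaling. So did 24 of 25 tested members of the Sfmbt2 cluster, 19 under every scaling, and 12 of 13 of the miR-17-92 cluster and its paralogs, 7 under every scaling. Of all 527 tested miRNAs 301 were called lower, 211 of them under every scaling. Camera did not separate the erythroid or the miR-17-92 list from the other miRNAs (adjusted p = 0.12 and 0.0824). Higher in O-DIO were the 3 miR-29 family members, which repress collagen genes, most liver-enriched miRNAs and several let-7 miRNAs, which accumulate as tissues differentiate. miR-802-5p, a miRNA that is raised in the liver of obese mice and impairs insulin action there, rose from 4.69 ± 3.5 to 299.9 ± 12.6 RPM (log2 fold change 5.90 ± 0.40 SE, adjusted p = 4.8e-06).

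Of 527 miRNAs with a mean of at least 1 RPM, 403 passed an adjusted p of 0.05 in limma, 102 higher and 301 lower in O-DIO. At least 2-fold changes were found in 61 of the higher and 253 of the lower miRNAs, or 126 and 185 after median-ratio rescaling. The values of the 2 groups did not overlap for 78.6% of tested miRNAs, where chance gives 10%. The median log2 fold change over all tested miRNAs was -0.93, so the split depended on the scaling. Rescaling by the median ratio shifted the fold changes by 0.77 and gave 167 higher and 223 lower (42.8% higher instead of 25.3%), and quantile normalization shifted them by 1.37 and gave 236 higher and 169 lower (58.3% higher). Under all 5 scalings used, 97 of the called miRNAs had a positive fold change and 211 a negative one, and the direction of the remaining 95 depended on the scaling. A count test on the recovered whole reads (edgeR, TMM scaling) called 190 higher and 243 lower of 604 tested, and 320 of its calls were also called, with the same sign, in the limma fit. Fold changes below are on the log2(RPM + 1) scale of the deposited values, which understates the change of low miRNAs, and printed list medians are also given after the median-ratio rescaling, with the list counts where these change.

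**Figure D1:**
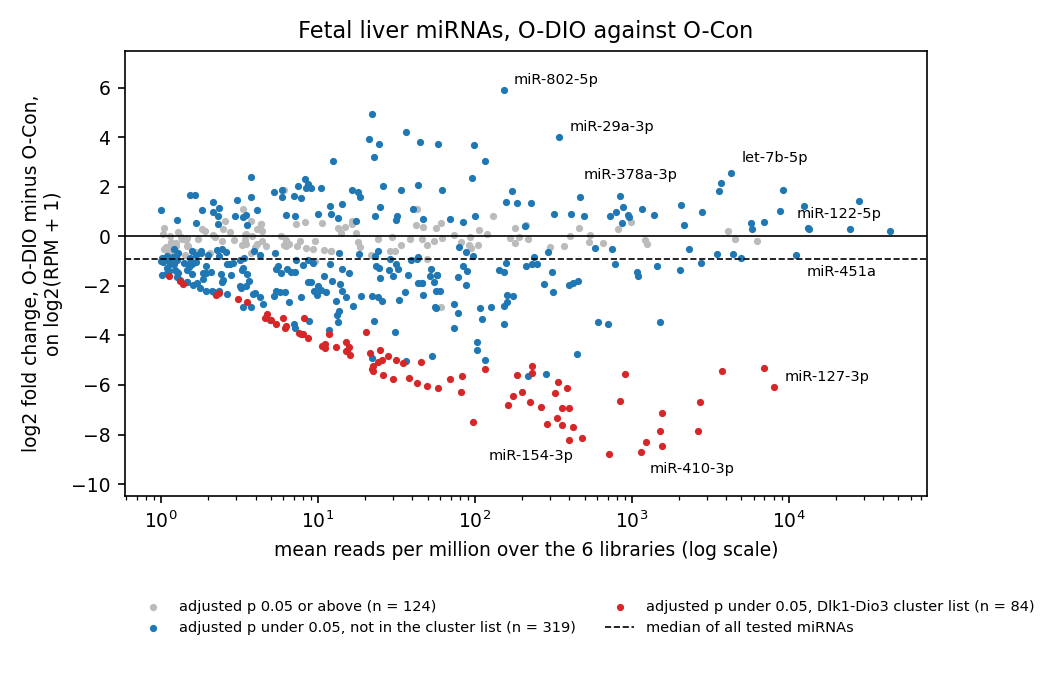
Log2 fold change on log2(RPM + 1), O-DIO minus O-Con, against the mean RPM over the 6 libraries on a log axis, for the 527 tested miRNAs, 1 point each. All 84 points of the Dlk1-Dio3 cluster list (red) lie below 0, and the dashed line marks the median of all tested miRNAs, -0.93, which moves to -0.24 after median-ratio rescaling.

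The Dlk1-Dio3 cluster held the 10 largest falls. miR-154-3p fell from 1434 ± 276 to 2.23 ± 0.12 RPM (log2 fold change -8.78 ± 0.20, adjusted p = 2.9e-08), and miR-410-3p from 2290 ± 848 to 4.27 ± 0.92 RPM (-8.72). miR-341-3p, miR-433-3p, miR-376b-3p, miR-409-3p, miR-431-5p, miR-369-3p, miR-487b-3p and miR-543-3p followed, with log2 fold changes of -8.48, -8.31, -8.21, -8.16, -7.86, -7.85, -7.68 and -7.63. The most abundant members were miR-127-3p, which fell from 15836 ± 1848 to 235 ± 36.5 RPM (-6.07), miR-411-5p, which fell from 13471 ± 975 to 342 ± 32.6 RPM (-5.30), and miR-379-5p (-5.45). miR-127-3p is known from the placenta, where it represses the retrotransposon-derived gene Rtl1 in antisense. The median log2 fold change of the 84 members was -5.35, or -4.62 after median-ratio rescaling, and every member was lower under all 5 scalings. The list stood apart from the other miRNAs (camera, adjusted p = 1.1e-20). With an estimated correlation between members neither it nor any other list passed in camera (adjusted p = 0.399 for this list). In the GRCm38 annotation the 84 miRNAs lie in 3 runs of neighbouring hairpins, with 2 further tested miRNAs, miR-3544-5p and miR-1188-5p, which were also lower (-2.08 and -2.85, named after their values were seen).

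**Figure D2:**
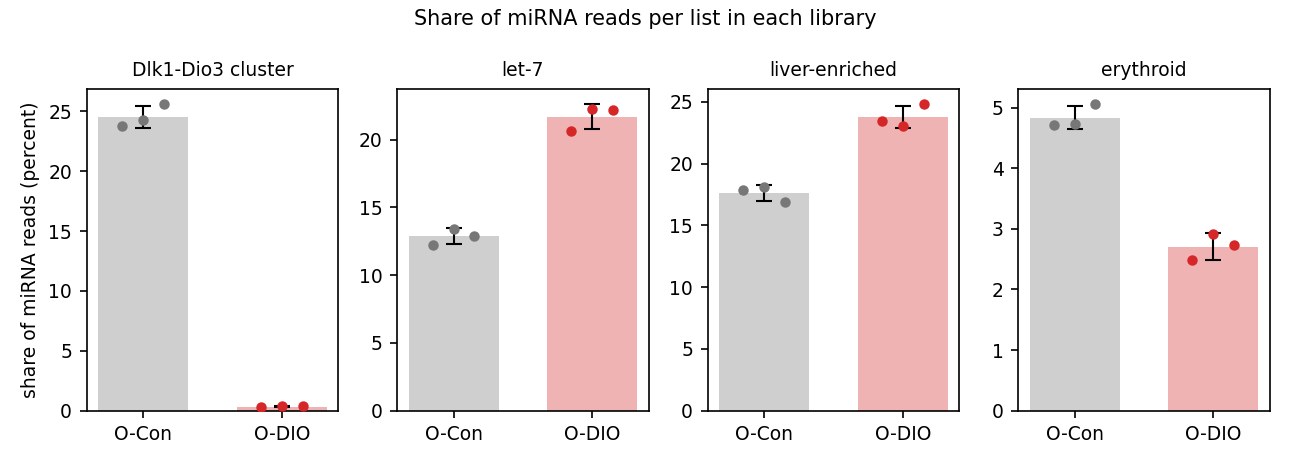
Share of miRNA reads, in percent, taken by 4 miRNA lists in each library; bars are group means, error bars 1 SD and points the 3 libraries of each group. The cluster's share was 24.6% in O-Con and 0.335% in O-DIO, the let-7 share 12.9% and 21.7%, the liver-enriched share 17.6% and 23.8% and the erythroid share 4.83% and 2.71%.

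Of 25 tested members of the Sfmbt2 cluster, a rodent-specific imprinted family expressed from the paternal allele, 24 fell and none rose. miR-467a-5p fell from 299.7 ± 152 to 51.5 ± 7.01 RPM (log2 fold change -2.41), miR-297a-5p from 97.9 ± 7.05 to 13.2 ± 3.99 RPM (-2.83) and miR-467e-5p from 73.0 ± 16 to 18.8 ± 3.0 RPM (-1.89); the first and last of these lost their call after quantile normalization (adjusted p = 0.0715 and 0.396). The list's median was -1.83, or -1.08 after rescaling, 19 of the 24 kept their direction under all 5 scalings, 21 were lower after median-ratio rescaling, and camera gave an adjusted p = 0.0178 (adjusted p = 0.614 with an estimated correlation). Members of this family are near-identical copies whose reads the counting could have split, so single values are uncertain. The list of miRNAs tied to liver proliferation and fetal growth moved both ways, with 4 of 12 higher and 6 lower, all 10 in the same direction under every scaling (camera, adjusted p = 0.767). After median-ratio rescaling 6 were higher and 6 lower. Its median was -0.97 (-0.14 after rescaling) and its mean -1.40, while the mean lay only -0.08 below that of the other miRNAs and camera's sign was positive. miR-675-3p, made from the imprinted H19 transcript, fell from 1111 ± 127 to 100.5 ± 2.63 RPM (-3.45), and miR-483-5p, from an intron of the imprinted growth factor gene Igf2, fell from 226 ± 56.6 to 6.31 ± 2.63 RPM (-4.99). These 2 were singled out after their values were seen. In the same list miR-378a-3p, encoded within the metabolic coactivator gene Ppargc1b, rose from 1346 ± 129 to 6031 ± 368 RPM (2.17), miR-21a-5p from 1595 ± 522 to 5630 ± 1455 RPM (1.84) and miR-23b-3p from 1237 ± 362 to 2906 ± 363 RPM (1.26).

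Liver-enriched miRNAs were mostly higher in O-DIO: 9 of 13 rose and 2 fell, 8 of the 9 rises and neither fall holding under all 5 scalings (10 higher and 0 lower after median-ratio rescaling). The median was 0.55, or 1.36 after rescaling, and camera gave an adjusted p = 0.000922 (adjusted p = 0.585 with an estimated correlation). miR-192-5p, which is abundant in liver, kidney and gut, rose from 7550 ± 1207 to 17590 ± 1913 RPM (log2 fold change 1.23, adjusted p = 6.0e-05). miR-802-3p, from the same hairpin as miR-802-5p, rose from 0.48 ± 0.43 to 43.7 ± 5.81 RPM (4.95). miR-122-5p, the most abundant miRNA and the main miRNA of hepatocytes, measured 40775 ± 3057 RPM in O-Con and 47818 ± 2249 RPM in O-DIO (0.23, adjusted p = 0.0151), turned to -0.12 when the cluster was left out of the scaling, and missed the threshold without O-Con 2 (adjusted p = 0.0511), without O-Con 3 (0.0575) or with a constant prior (0.187). Its other arm, miR-122-3p, did not pass (-0.20, adjusted p = 0.513, and 0.69 after rescaling).

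The other 4 most abundant miRNAs also passed the test. miR-22-3p rose from 15125 ± 1227 to 41176 ± 3343 RPM (log2 fold change 1.44, adjusted p = 1.8e-06) under all scalings. miR-26a-5p (0.31) and let-7a-5p (0.34) were higher in the deposited values and turned to -0.04 and -0.01 with the cluster left out of the scaling. Neither passed in limma with a constant prior (adjusted p = 0.0785 and 0.06). miR-126a-3p, made by endothelial cells from the Egfl7 gene, measured 22100 ± 1635 and 27136 ± 3117 RPM (0.29, adjusted p = 0.0248), with -0.06 in the same scaling and -0.52 after quantile normalization. Its call was lost without O-Con 2 (adjusted p = 0.081), O-DIO 1 (0.0731) or O-DIO 2 (0.0594), with no filter (0.0547) and with a constant prior (0.136). The 10 most abundant miRNAs took 45.7% ± 0.53 of miRNA reads in O-Con and 63.1% ± 0.56 in O-DIO, and 1188 ± 31.9 and 973 ± 32.4 miRNAs were detected. For these and the other shares given here, the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow (0.108 adjusted over 14 measures). 

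Of 9 let-7 miRNAs, 6 rose and 2 fell, with 4 of the rises and 1 fall, that of let-7e-5p (-1.20, named after its value was seen), keeping their direction under all 5 scalings (7 higher and 0 lower after median-ratio rescaling). let-7c-5p rose from 3988 ± 102 to 14466 ± 396 RPM (log2 fold change 1.86) and let-7f-5p from 5801 ± 136 to 11727 ± 633 RPM (1.01). The median was 0.34, or 1.24 after rescaling, and camera gave an adjusted p = 0.0178 (adjusted p = 0.399 with an estimated correlation). All 3 miR-29 miRNAs rose under every scaling: miR-29a-3p from 38.8 ± 2.18 to 649 ± 123 RPM (4.01), miR-29c-3p from 13.3 ± 1.11 to 185 ± 23.7 RPM (3.69) and miR-29b-3p from 30.0 ± 4.14 to 162 ± 41.3 RPM (2.37). The camera test of this family gave an adjusted p = 0.00168 (adjusted p = 0.575 with an estimated correlation). let-7 and miR-29 members differ from each other by few bases, so reads could have been shared between them.

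Besides miR-802 and miR-29, the 10 largest rises included miR-203b-5p (4.22, from 2.97 ± 1.62 to 69.5 ± 9.60 RPM) and miR-203-5p (3.93). In the GRCm38 annotation the miR-203 hairpin overlaps the hairpin Gm51289 by 60 nucleotides, and no overlap is listed under the name miR-203b. Overlaps were found without regard to strand, so this does not show that these 2 miRNAs share reads. The largest rises also included miR-383-5p (3.80), miR-3965 (3.74), miR-1948-3p (3.71) and 1 predicted miRNA (3.20, from 3.61 ± 0.42 to 42.2 ± 11.2 RPM). miR-3965 varied widely in O-DIO, at 46.7 ± 42.6 RPM. All 10 had positive fold changes under every scaling. Of 35 tested predicted miRNAs, 27 passed the test, and predicted miRNAs took 0.280% ± 0.023 of miRNA reads in O-Con and 0.172% ± 0.033 in O-DIO.

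miRNAs linked to lipid and insulin metabolism went both ways: 8 of 24 rose and 7 fell, 7 and 4 of them under all scalings, and 16 rose and 4 fell after median-ratio rescaling. miR-378a-3p and miR-802-5p, given above, were among the rises. miR-143-3p, raised in the liver of obese mice, did not pass (4777 ± 1183 and 4366 ± 399 RPM, -0.11, adjusted p = 0.591) and reversed to 0.79 after median-ratio rescaling. Camera placed the list above the other miRNAs (adjusted p = 0.0354, adjusted p = 0.614 with an estimated correlation, and 0.0657 without O-DIO 1), although its median was -0.06 (0.83 after rescaling) and its mean 0.02, so its members did not rise on balance (fry, p = 0.821). Of 6 miRNAs induced in inflammation 2 were higher, both under all scalings, and 1 lower, but 5 were higher and 1 lower after median-ratio rescaling (median 0.25, or 1.15 after rescaling; camera, adjusted p = 0.128). Among them were miR-21a-5p, given above, miR-146a-5p (0.06, adjusted p = 0.722) and miR-125b-5p (0.45, adjusted p = 0.402). Both passed after median-ratio rescaling (0.95, adjusted p = 0.000319, and 1.34, adjusted p = 0.021), after quantile normalization (1.35 and 1.99) and in edgeR (0.94 and 1.38) and DESeq2 (0.96 and 1.41). miR-146a-5p also passed with the 5 most abundant miRNAs left out of the scaling (0.47), and was -0.29 with the cluster left out. In the miR-34 family, targets of p53, 2 of 3 tested members were lower, miR-449a-5p (-1.55) and miR-34c-5p (-0.95), and both turned positive after quantile normalization (0.17 and 0.20). After median-ratio rescaling 1 member was higher and 0 lower. The family's median was -0.95 (-0.51 after rescaling), while camera's sign was positive (adjusted p = 0.947). miR-34a-5p was 763 ± 74.2 and 1227 ± 557 RPM (0.57, adjusted p = 0.174), and passed without O-DIO 2 (1.00, adjusted p = 0.0021), after median-ratio rescaling (1.46, adjusted p = 0.0065), after quantile normalization (1.68), with the 5 most abundant miRNAs left out of the scaling (0.98), and in edgeR (1.58) and DESeq2 (1.61).

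Markers of other cell types also differed between the groups, in both directions. All 8 erythroid miRNAs fell, 7 of them under every scaling and 7 past the threshold after median-ratio rescaling, with a median of -3.39, or -2.56 after rescaling. miR-144-3p fell from 1294 ± 292 to 111 ± 26.5 RPM (log2 fold change -3.54) and miR-486a-5p from 199.9 ± 96.7 to 21.5 ± 18.3 RPM (-3.35). The hairpin of the latter overlaps that of miR-486b in the GRCm38 annotation, so their reads may not be separable. miR-451a, encoded beside miR-144, fell from 13934 ± 788 to 8322 ± 458 RPM (-0.74), which turned to 0.15 after median-ratio rescaling. Camera did not separate the erythroid list from the other miRNAs (adjusted p = 0.12), while fry found that its members fell on balance in the deposited values (adjusted p = 0.000148). In these values the median log2 fold change of all tested miRNAs was -0.93. Of 10 white blood cell miRNAs 6 fell and 1 rose, 3 and 1 of them under all scalings, but 4 fell and 4 rose after median-ratio rescaling (median -1.01, or -0.20 after rescaling; camera, adjusted p = 0.947). Myeloid miR-223-3p fell from 866 ± 191 to 30.9 ± 2.82 RPM (-4.75), lymphoid miR-150-5p rose from 75.2 ± 14.2 to 267 ± 31.5 RPM (1.83, named after its value was seen), miR-146a-5p is given above, and miR-181a-5p was lower (-0.71) but at 0.19 after median-ratio rescaling. The miR-17-92 cluster and its paralogs, which promote proliferation, had 12 of 13 members lower, 7 under all scalings and 7 past the threshold after median-ratio rescaling, with a median of -1.37 (-0.49 after rescaling; camera, adjusted p = 0.0824). miR-19b-3p fell from 519 ± 159.6 to 106 ± 10.8 RPM (-2.24) and miR-93-5p from 1068 ± 88.7 to 489 ± 58.0 RPM (-1.13). miR-19b-3p lost its call after quantile normalization (-0.50, adjusted p = 0.163), and miR-93-5p lost its call there (-0.18), after median-ratio rescaling (-0.24, adjusted p = 0.156), in edgeR (adjusted p = 0.132) and in DESeq2 (adjusted p = 0.388). miR-92a-3p (-0.50, adjusted p = 0.0361) turned to 0.40 after median-ratio rescaling and did not pass without O-Con 2 (adjusted p = 0.112), O-Con 3 (0.125), O-DIO 1 (0.0838) or O-DIO 3 (0.107).

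**Figure D3:**
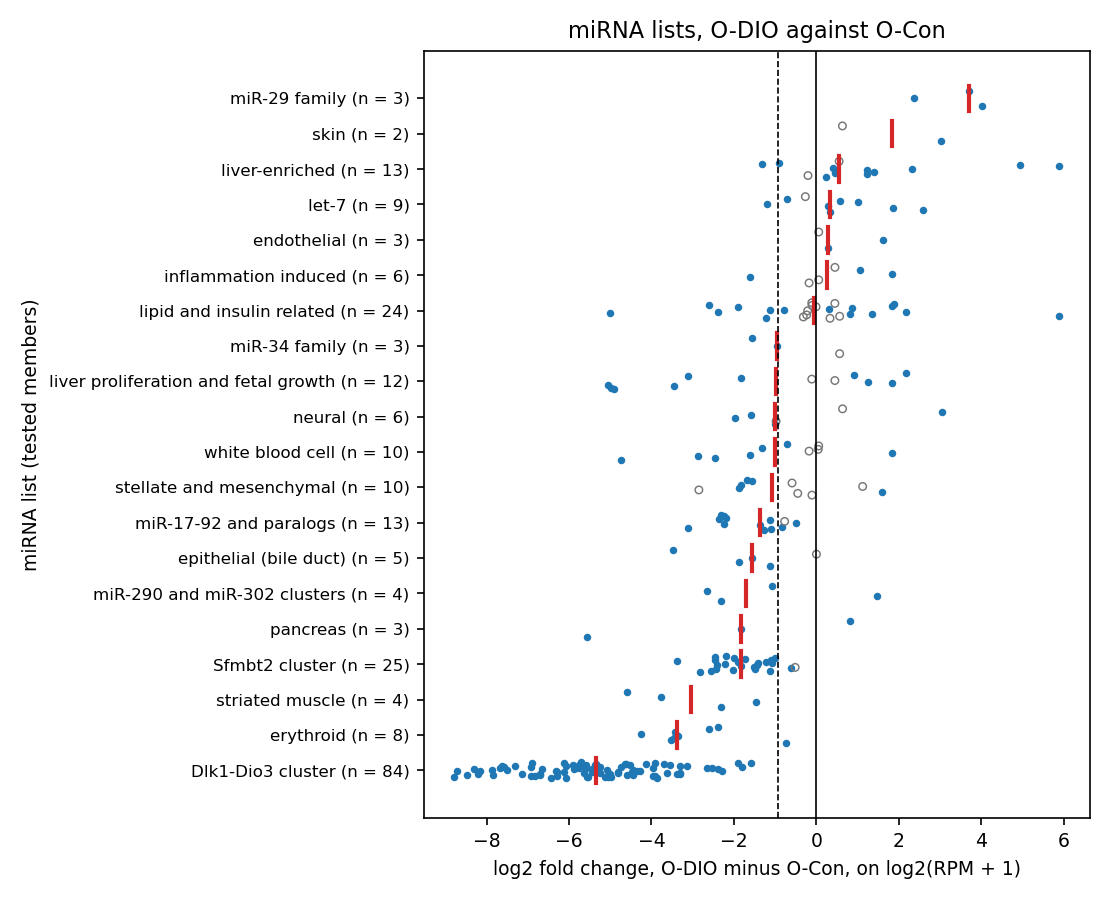
Log2 fold change on log2(RPM + 1), O-DIO minus O-Con, of the tested members of each miRNA list, 1 point per miRNA; filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians. The solid line is 0 and the dashed line the median of all tested miRNAs, -0.93; list medians run from -5.35 (Dlk1-Dio3 cluster) to 3.69 (miR-29 family), or -4.62 and 4.55 after median-ratio rescaling, and those near 0 or the dashed line can change sign with the scaling.

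Striated muscle miRNAs were low and fell in all 4 tested members under every scaling: miR-499-5p, from an intron of the myosin gene Myh7b, fell from 198 ± 15.9 to 7.33 ± 1.26 RPM (log2 fold change -4.59), miR-206-3p from 22.8 ± 10.9 to 0.64 ± 0.14 RPM (-3.77) and miR-1a-3p from 7.25 ± 1.42 to 0.67 ± 0.30 RPM (-2.30). The list took 0.0711% of miRNA reads in O-Con and 0.00291% in O-DIO (camera, adjusted p = 0.198). Of 3 pancreatic miRNAs 2 fell and 1 rose under all scalings: miR-375-3p, abundant in islet cells, fell from 559.9 ± 164 to 10.6 ± 0.46 RPM (-5.56), and miR-7a-5p rose from 362 ± 75.4 to 635 ± 51.3 RPM (0.83) but did not pass with the cluster left out of the scaling (0.48, adjusted p = 0.0653); the share was 0.284% and 0.206% (camera, adjusted p = 0.947). Of 5 epithelial miRNAs 4 fell, 2 under all scalings and 3 after median-ratio rescaling (camera, adjusted p = 0.435). miR-429-3p fell from 2765 ± 209 to 250.2 ± 41.9 RPM (-3.47), whereas miR-200a-3p (-1.13) and miR-200c-3p (-1.56) became positive after quantile normalization (0.63 and 0.13). Neural miRNAs were 3 of 6 lower and 1 higher, with 2 falls and the rise, that of miR-137-3p (3.06), under all scalings; miR-128-3p (-1.96) and miR-138-5p (-1.59) fell, and both lost their call after quantile normalization (adjusted p = 0.334 and 0.926). After median-ratio rescaling 3 were lower and 2 higher. Their median was -0.99 (-0.64 after rescaling), their mean -0.31 and camera's sign positive (adjusted p = 0.846), and their share was 0.0507% and 0.0213%. Of the 2 skin miRNAs, too few for a list test, miR-203-3p rose from 25.0 ± 6.88 to 208 ± 32.6 RPM (3.03), and miR-205-5p did not pass (0.63, adjusted p = 0.176) but did without O-Con 1 (1.02, adjusted p = 0.0239), after median-ratio rescaling (1.31, adjusted p = 0.00543), after quantile normalization (2.02), with the 5 most abundant miRNAs left out of the scaling (0.94, adjusted p = 0.049), and in edgeR (1.55) and DESeq2 (1.58).

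Among 10 stellate and mesenchymal miRNAs 4 fell and 1 rose, 3 and 1 under all scalings, and 3 fell and 2 rose after median-ratio rescaling. miR-199a-5p fell from 663 ± 242 to 175 ± 32.4 RPM (log2 fold change -1.87) and lost its call after quantile normalization (-0.35, adjusted p = 0.271), and miR-145a-5p did not pass (-0.45, adjusted p = 0.362, and 0.43 after median-ratio rescaling). The list's median was -1.08 (-0.21 after rescaling) and its mean -0.82, while camera's sign was positive (adjusted p = 0.866). miR-199a-3p and miR-199b-3p, whose hairpins share at least 21 nucleotides on that arm, were assigned almost wholly to 1 name or the other in each library. The list counts them separately, with neither past the threshold, and their sum was 150.7 ± 5.52 RPM in O-Con and 55.9 ± 4.69 RPM in O-DIO. Of 3 endothelial miRNAs, 2 were higher (3 after median-ratio rescaling), miR-126a-5p (from 423 ± 146 to 1264 ± 105 RPM, 1.63) under all scalings and miR-126a-3p as described, and miR-126b-3p did not pass (0.06, adjusted p = 0.79), with a camera adjusted p = 0.12 for the list. miR-126b-3p was -0.21 with the cluster left out of the scaling, and passed as higher after median-ratio rescaling (0.74, adjusted p = 0.0107), after quantile normalization (1.36) and in edgeR (0.95) and DESeq2 (0.97). Of the miR-290 and miR-302 clusters, typical of embryonic stem cells, 4 members were tested, none of them named miR-302. These 4 were low in both groups, and 3 fell and 1 rose, with 2 and 1 after median-ratio rescaling (camera, adjusted p = 0.947). miR-293-3p fell from 12 ± 2.59 to 1.08 ± 0.47 RPM (-2.65) and miR-292b-5p rose from 1.12 ± 0.34 to 4.94 ± 1.25 RPM (1.48), both under all scalings. miR-294-3p (-1.08, adjusted p = 0.0191) did not pass without O-DIO 3 (adjusted p = 0.0697) and was 0.13 after quantile normalization. In each list, the numbers higher and lower were the same adjusted over the list alone as over all 527 miRNAs.

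**Figure D4:**
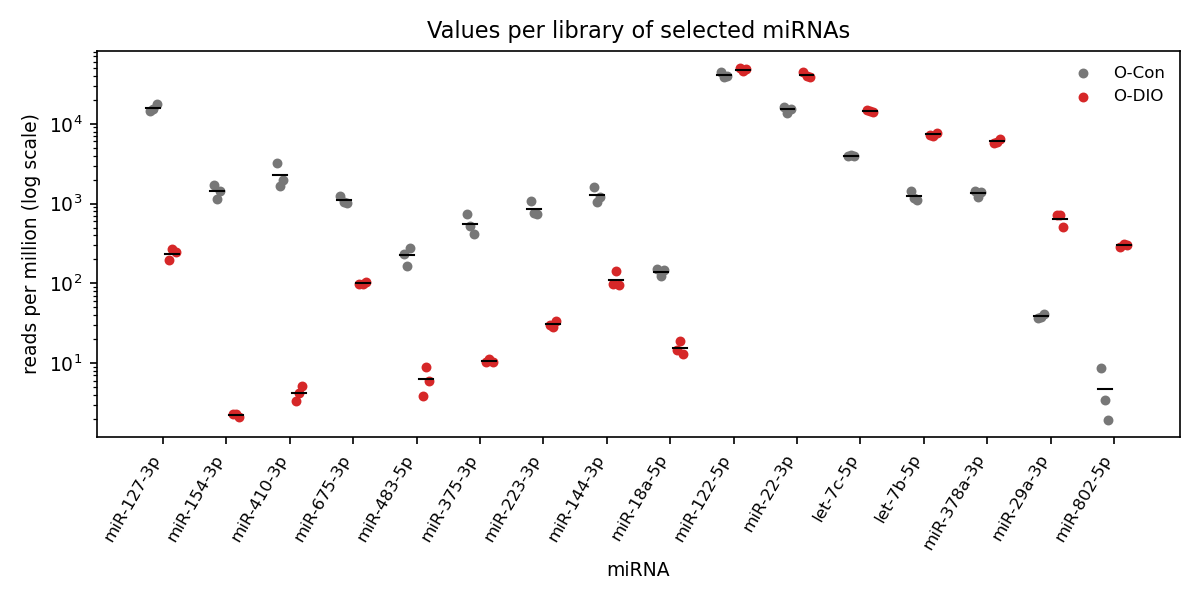
RPM on a log axis of 16 miRNAs in each of the 3 O-Con (grey) and 3 O-DIO (red) libraries, with group means as black bars. The miRNAs were picked after their values were seen to show both directions; miR-122-5p is the one whose groups lie closest, at 40775 and 47818 RPM, and its direction turns with the cluster left out of the scaling.

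The ratio of the 5p to the 3p arm of a hairpin was taken after adding 1 RPM to each arm, so it depends on the library scaling where an arm is low. Of 138 hairpins with both arms tested, 72 changed their ratio (adjusted p under 0.05 in limma), 32 toward the 5p arm and 40 toward the 3p arm, but many had 1 arm near the floor in O-DIO, where the pseudocount sets the ratio. With both arms at a mean of at least 10 RPM in both groups, 13 of 32 hairpins changed, 6 toward the 5p arm and 7 toward the 3p arm, and the more abundant arm was the same in both groups for each. These hairpins were named after their values were seen. The log2 ratio of miR-21a moved from 5.91 ± 0.15 to 7.86 ± 0.57 (change 1.95, adjusted p = 0.00687), that of miR-191 from 6.16 ± 0.22 to 7.35 ± 0.02 (1.20) and that of miR-126a from -5.75 ± 0.47 to -4.42 ± 0.12 (1.33). The ratio of miR-192 moved toward the 3p arm by -0.84 and that of miR-378a by -0.83 (adjusted p = 0.0258 each).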

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

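Tests with edgeR or DESeq2, scaling without the Dlk1-Dio3 cluster, leaving the cluster or the 5 most abundant miRNAs out of the test, known miRNAs alone and the 10 RPM arm filter were chosen only after the results were seen. Of 74 named miRNAs, 47 kept their side of the threshold in every setting run for them, without a change of direction where either fit passed. A change of direction between fits that both missed the threshold was not counted, as for miR-122-3p (-0.20, and 0.69 after median-ratio rescaling). By the same rule, 1578 of 1675 values compared were unchanged, and 337 of 374 values of the 19 list tests. The count of calls was 403 and ran from 263 to 527 over 25 alternatives, which does not say that the same miRNAs were called. Without 1 library it ran from 372 to 412, with 85 to 113 higher and 282 to 299 lower, and 63 to 67 changed arm ratios. The list of lipid and insulin related miRNAs ran from 1.35 to 1.48 (log2, mean minus that of the other miRNAs) without 1 library, and lost its call without O-DIO 1 (adjusted p = 0.0657, range over its alternatives 0.0128 to 0.821). Except where a sentence gives a cause, the cause of a change was not tested.

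A filter at 10 RPM in 3 libraries tests fewer miRNAs and left 263 calls, 187 of them lower, and the Sfmbt2 list at -0.54 lost its call (adjusted p = 0.0584). A log2 fold change of at least 1 left 61 higher by construction. Median-ratio scaling gave 167 higher and reversed miR-143-3p (0.79), miR-451a (0.15), miR-181a-5p (0.19) and miR-92a-3p (0.40). edgeR with TMM gave 190 higher and 0.76, 0.13, 0.16 and 0.34 for these 4, and DESeq2 gave 200 higher and 0.78, 0.14, 0.18 and 0.35. Quantile normalization gave 236 higher and 169 lower and reversed miR-126a-3p (-0.52), miR-145a-5p (1.33), miR-200a-3p (0.63), miR-200c-3p (0.13), miR-92a-3p (0.41), miR-449a-5p (0.17), miR-34c-5p (0.20) and miR-294-3p (0.13). In the same setting the lists lipid and insulin related (1.33), let-7 (0.79), Sfmbt2 (-0.44) and miR-29 (4.90) lost their calls and erythroid (-1.66) gained one. Scaling without the cluster reversed miR-122-5p (-0.12), miR-126a-3p (-0.0564), miR-26a-5p (-0.0438) and let-7a-5p (-0.0067), and the lipid (1.36) and let-7 (1.78) lists lost their calls.

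With no filter the lipid list lost its call (0.52), while the erythroid (-2.49), endothelial (1.05), epithelial (-1.12), striated muscle (-1.10) and miR-17-92 (-1.06) lists gained one. With the cluster not tested the lipid (0.84) and let-7 (1.08) lists lost their calls, and the erythroid (-2.46) and miR-17-92 (-1.12) lists gained one; here the set of other miRNAs had changed by construction. With the correlation between members estimated in camera all 6 called lists lost their calls at unchanged differences: liver-enriched 2.64, lipid 1.41, let-7 1.85, Dlk1-Dio3 -4.78, Sfmbt2 -0.50 and miR-29 4.71. No list passed there, and the lowest unadjusted camera p was 0.0237, for the Dlk1-Dio3 cluster. For let-7 the estimated correlation was -0.011, below the preset 0.01, and its unadjusted camera p still rose from 0.00469 to 0.042. Correlation between members therefore does not account for its lost call. fry tests the mean of a list itself, not its difference from other miRNAs. Its means were 0.0202 for the lipid list, which lost its call and had a negative sign in fry, where members are weighted by their spread, and for lists that gained one -2.97 (erythroid), -1.19 (white blood cell), 0.66 (endothelial), -1.61 (epithelial), -3.03 (striated muscle), -2.19 (pancreas), -1.65 (miR-17-92) and -1.14 (miR-290 and miR-302). The neural (-0.31), miR-34 (-0.64) and liver proliferation (-1.40) lists passed as lower in fry, against a positive sign in camera. fry was run only on the deposited values, where the median log2 fold change of all tested miRNAs was -0.93. A list can therefore pass as lower in fry without lying below the other miRNAs, and fry was not run after rescaling.

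Calls of other named miRNAs changed without a change of direction. Quantile normalization ended those of miR-199a-5p (-0.35), miR-128-3p (-0.22), miR-138-5p (-0.02), miR-467a-5p (-0.65), miR-467e-5p (-0.17), miR-93-5p (-0.18) and miR-19b-3p (-0.50). It gives the most abundant miRNA the same value in each library, so the lost call of miR-122-5p follows by construction and says nothing about its change. Median-ratio scaling ended those of miR-93-5p (-0.24), miR-200a-3p (-0.24), miR-449a-5p (-0.69), miR-34c-5p (-0.51) and miR-294-3p (-0.47), and gave calls to miR-146a-5p (0.95), miR-125b-5p (1.34), miR-126b-3p (0.74), miR-205-5p (1.31) and miR-34a-5p (1.46), which also passed after quantile normalization, in edgeR and in DESeq2. A constant prior ended the calls of miR-122-5p (adjusted p = 0.187), miR-126a-3p (0.136), miR-26a-5p (0.0785), let-7a-5p (0.06) and miR-92a-3p (0.0659). Scaling without the cluster ended that of miR-7a-5p (0.48) and gave one to miR-143-3p (-0.46).

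Counting a miRNA as detected at 10 RPM gave a difference of -86.7 miRNAs between the groups. Shares without the most abundant miRNA differed by 4.25 (liver-enriched), -0.0778 (striated muscle), -0.0328 (neural), 0.0699 (skin), -27.7 (Dlk1-Dio3) and 10.9 (let-7) percentage points, since the denominator was smaller and the liver-enriched list lost a member, miR-122-5p. With both arms at 10 RPM, 13 arm ratios changed among fewer hairpins. With the replicate number as a block, 390 miRNAs were called, 98 higher and 292 lower, and 65 arm ratios changed, with no call of a named miRNA or list changed. Libraries of the same number were correlated after removal of the group means at -0.43, -0.223 and -0.071, and those of different numbers at -0.253 to 0.37. This gave no sign that the numbers pair them. With 3 libraries per group these correlations depend on each other, so a shared day or batch is not excluded. Alternatives planned for deposited raw counts (library totals alone, upper-quartile factors, limma-voom, other prior counts) were not run because the values are RPM. Depth limits the low miRNAs: 3 reads are 0.159 to 0.180 RPM. In the simulation, whose settings were simpler than the real data, limma recovered 43% of 2-fold changes. A miRNA that did not pass may still have changed.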

Other observations

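Outside the lists fixed in advance, other groups of neighbouring or related miRNAs changed, and those named in this paragraph were picked for it after their values were seen. In a run of 5 X-linked hairpins, all 10 tested miRNAs were lower in O-DIO under all 5 scalings, with a median log2 fold change of -2.20. miR-322-5p, which slows the cell cycle in muscle precursors, fell from 1643 ± 49.6 to 548 ± 93.6 RPM (-1.60, adjusted p = 3.9e-05), miR-542-5p from 438 ± 15.8 to 116 ± 8.20 RPM (-1.90) and miR-351-5p from 190 ± 14.4 to 25.0 ± 5.78 RPM (-2.90). All 4 tested arms of miR-296 and miR-298, encoded near the imprinted Gnas locus, were also lower under all scalings, with a median of -2.73. miR-296-5p fell from 281 ± 196 to 38.0 ± 2.57 RPM (-2.65) and varied widely in O-Con. The main arms of the miR-30 family, which are high in differentiated epithelial cells, rose under all scalings: miR-30d-5p from 530 ± 40.8 to 1052 ± 112 RPM (0.98), miR-30b-5p from 704 ± 108 to 1031 ± 25.6 RPM (0.56), miR-30a-5p from 290 ± 116 to 523 ± 32.4 RPM (0.92), miR-30c-5p from 109 ± 59.0 to 260 ± 17.6 RPM (1.36) and miR-30e-5p from 25.7 ± 10.1 to 54.4 ± 8.58 RPM (1.11). Of the 3p arms of this family miR-30c-2-3p passed (0.72), while miR-30a-3p (0.37), miR-30e-3p (0.40), miR-30b-3p (-0.38), miR-30d-3p (-0.49) and miR-30c-1-3p (-0.32) did not, so the family did not move as a whole.

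In the 3 patterns below, the 5 tests of the Dlk1-Dio3 cluster and the test of shared reads were chosen only after the results were seen. The miRNAs of the cluster were lower in O-DIO. Library scaling was excluded as the whole cause, since the highest cluster median over the 4 other scalings was -3.88, and a change confined to the cluster was excluded as well, since 69.1% of 443 tested miRNAs outside it passed after median-ratio scaling. Muscle, neural or pancreatic tissue in the O-Con libraries would bring its own abundant miRNAs, but these 3 lists together took 0.406% of O-Con miRNA reads against 24.6% for the cluster. Each of the 3 shares was higher in O-Con than in O-DIO, that of striated muscle at 0.0711% and 0.00291%, so a small amount of such tissue is not excluded. How much of the cluster such tissue would carry was not measured, and other tissues were not tested. A candidate explanation is lower output of imprinted loci in general. The 17 miRNAs listed for H19, Igf2, Mest and Sfmbt2 had a median of -1.45 relative to all tested miRNAs. Of 10000 random lists of similar abundance, 0.02% lay at or below this value. Each random list drew single miRNAs from outside the cluster and did not keep miRNAs of one transcript together. The share is therefore not a test of these loci. Adding the 14 tested Sfmbt2 members that the list of 17 had left out gave -1.09 over 31 miRNAs. Several of these values were known when the list was made and 11 of the first 17 come from Sfmbt2, the loci include maternally and paternally expressed ones, and no allele was measured, so this remains a hypothesis. It was not tested apart from a later liver stage, the candidate given below for the width of the difference.

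The second pattern is the width of the difference, 403 of 527 miRNAs. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 split, the real one, gave as many calls, with 403 against 2 for the highest other. Without the 5 most abundant miRNAs in the scaling and the test 387 passed, so these 5 did not set the number of calls. The Dlk1-Dio3 cluster stayed in that scaling, and a count of calls cannot exclude a scale set by abundant miRNAs. The share of calls that were higher ran from 18% with the cluster left out of the scaling to 58.3% after quantile normalization. A later liver stage in the O-DIO libraries is a candidate explanation: 8 miR-30 miRNAs (median 0.48, 4 of them past the threshold) lay above 10 of the X-linked group (median -2.23) by 2.71 (exact permutation p = 0.0016 over 43758 arrangements), although the idea came from these data, miRNAs of one transcript are not independent, miR-30c-1-3p (-0.32, adjusted p = 0.453) had been left off the list, and both lists were set once miR-30a-5p, miR-30c-5p and miR-322-5p, which they leave out, had been seen to differ in these directions, so the p is not that of an independent test. The maternal diet itself, other differences in tissue make-up and any batch, dissection or age difference that coincides with the groups stay open and were not tested, and the labels give the same gestational day for all 6 libraries.

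The third pattern is uneven values of miRNAs whose hairpins share at least 21 nucleotides on the named arm, which does not make their mature sequences identical. Reads shared between such miRNAs were tested over 10 pairs, and the spread of the sum within groups was 0.85 of that of the members at the median, which does not decide the matter for the pairs as a set. In 2 pairs the sum varied far less than its members, miR-199a-3p with miR-199b-3p (ratio 0.03) and let-7a-1-3p with let-7c-2-3p (0.23), so that reads may have been assigned to 1 name or the other library by library. No biological explanation was tested for this pattern.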
